A study of Rattus norvegicus with 8 samples.

How the data were processed

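Gene expression was measured with 8 Affymetrix Rat Gene 1.0 ST arrays in the ductus arteriosus (DA) and the aorta of Brown-Norway (BN) and Fischer344 (F344) rat neonates, 1 h after birth. Per the labels, each of the 4 combinations of strain and tissue had 2 replicate arrays, RNA came from pooled tissues, and 150 ng of total RNA was labelled with biotin for each array. The deposited values were taken as log2 from their range, which was between 1.07 and 14.2 over all arrays, and the submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets. The version and settings of RMA, any filter and the genome build of the probe annotation are not given in the sources used here. The values were used as deposited. The number of arrays limits the precision, and no measure of depth applies to them.

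The table held 29215 probe sets and 0 columns of other samples. The platform annotation of 2016 gave 1 gene symbol for 15310 probe sets and several for 323, and 13582 probe sets were not listed in it and are unnamed here. Of the probe sets with 1 symbol, 15279 had an Entrez identifier in the RefSeq gene table (assembly GRCr8) and 31 did not, and the symbols were the same in both. RefSeq coordinates were not used, because the build behind the array annotation is not given. Where a gene had more than 1 probe set (527 genes), the probe set with the highest mean over all arrays was kept, which left 14506 genes. Of these, 1283 had symbols of olfactory, vomeronasal, taste or trace amine receptors and are called chemosensory receptor genes below, a class defined after the data were examined. Probe sets of multi-copy families such as these, or of the Spetex genes, can bind transcripts of related copies, so values of single members are uncertain.

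Differences were tested with limma (version 3.58.1, R version 4.3.3). One linear model with a mean for each of the 4 groups was fitted to all 8 arrays, so that the groups shared 1 estimate of the spread with 4 residual degrees of freedom, and variances were moderated with eBayes (5.2 prior degrees of freedom). The contrasts were DA minus aorta in each strain, BN minus F344 in each tissue, the interaction, and the tissue and strain differences averaged over the other factor. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Errors of differences are standard errors from the model, and group means are given with the SD over 2 arrays. A 2-fold difference is 1 on the log2 scale.

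Before the data were examined, 34 lists with 600 genes were fixed for vascular pathways and for cell types that the dissected tissue could hold. Of these genes 515 were tested, and 33 lists with at least 5 tested members entered camera with a preset correlation of 0.01, camera with a correlation estimated from the data, and fry, each adjusted over the lists within a contrast. The list of sex-linked genes had too few tested members. Whether tissue differences were smaller in BN was tested on the genes called in the averaged tissue contrast with roast, a rotation test (9999 rotations), because an exact permutation of strain labels within tissues has 36 arrangements and cannot go below a two-sided p of 0.0556. That selection is independent of the interaction only when all arrays are present.

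The rule for named genes was also fixed beforehand. For each contrast, the 8 genes with the largest positive and the 8 with the largest negative log2 difference were named among called genes of at least 2-fold whose arrays did not overlap between the groups and whose brighter group exceeded the median of all values, passing over predicted genes. If fewer than 5 passed, the 10 genes with the smallest p were named. To these were added up to 4 called members of each list with the largest differences, and 20 genes chosen for their place in ductus biology, of which 18 were tested; Ednra and Ednrb are not analysed here.

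The procedures were tested on simulated data made with the means and spreads of the 14506 genes. For DA against aorta in F344, 95% of 100 genes changed by 1 on the log2 scale and 100% of 100 genes changed by 2 were recovered, and 4.9% of calls were unchanged genes. For the interaction, 71% of genes changed by 1 were recovered. The simulated spread of a gene was alike in all groups and independent between genes. The BN DA replicates differed more (SD of the replicate difference 0.349, against 0.196 to 0.258 in the other groups), so recovery in the data may be lower. The alternatives tried were a mean-variance trend, robust moderation, leaving out dim genes, repeated quantile normalization, centring on brighter genes, the mean of a gene's probe sets, every probe set, array weights, the replicate number as a block, a 2-fold minimum, fits with the 4 arrays compared, each array left out, and, added after the data were seen, cyclic loess and leaving out chemosensory receptor genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Ribosomal protein genes were taken by their symbols after the data were seen.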

Results

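The ductus arteriosus (DA) is the fetal vessel that joins the pulmonary artery to the aorta and closes after birth. Its transcripts and those of the aorta were measured in neonates of the inbred rat strains Brown-Norway (BN), which has been used as a natural model of a ductus that stays open, and Fischer344 (F344), 1 h after birth. Each of the 4 groups held 2 arrays, and 14506 genes were tested. The labels do not state that replicates came from separate animals or litters, and RNA came from pooled tissues, so p-values measure only the spread between these samples. Median log2 values per array lay between 6.96 and 7.05. The first principal component held 53.9% of the variance and placed the F344 DA arrays at -30.7 and -37.5, the BN DA arrays at 0.3 and -9.87, and the aorta arrays between 14.7 and 27.5.

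The BN DA replicates differed more from each other than other replicates. The SD of the replicate difference over genes was 0.349 in BN DA, against 0.223 in F344 DA, 0.196 in F344 aorta and 0.258 in BN aorta, and 200 genes lay at least 1 log2 unit apart in BN DA, against 17 to 20 in the other groups. Markers of thymocytes and lymphocytes had a mean of 6.93 on BN DA replicate 1 and between 5.88 and 6 on the other 7 arrays. Erythroid markers were higher on replicate 1 than on replicate 2 in each group, with means of 8.14 and 7.36 in F344 DA, 7.59 and 7.01 in F344 aorta, 8.57 and 7.53 in BN DA, and 8.02 and 7.51 in BN aorta. The 71 ribosomal protein genes had means of 11.12 and 10.44 on BN DA replicates 1 and 2 and of 10.95 and 10.59 on those of BN aorta, against 10.83 to 10.89 on the F344 arrays. The 1283 chemosensory receptor genes, most of which encode olfactory and vomeronasal receptors, were dim on all arrays, with medians of 5.97 and 6.04 in F344 DA, 5.04 and 5.17 in F344 aorta, 5.29 and 5.61 in BN DA, and 4.93 and 5.09 in BN aorta.

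**Figure D1:**
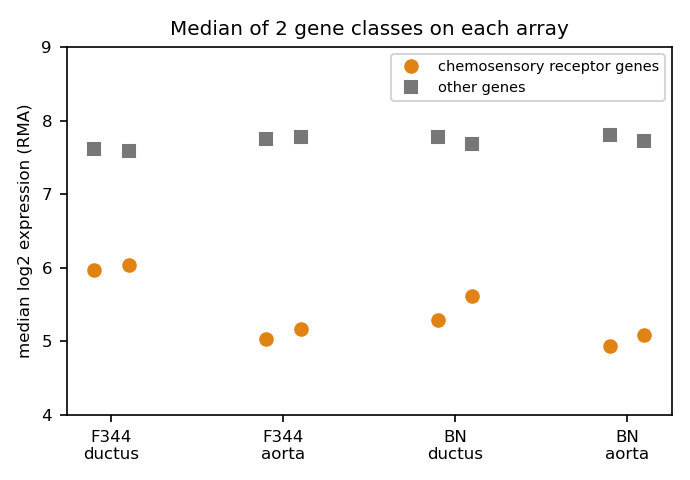
Median log2 expression (vertical axis) of the chemosensory receptor genes (circles) and of the other genes (squares) on each of the 8 arrays, by group. The receptor medians of the F344 DA arrays, 5.97 and 6.04, lie above those of the other 6 arrays.

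DA and aorta were first compared within F344, which shows how the vessels differ in this strain. Genes higher in DA were led by Tfap2b, the transcription factor mutated in Char syndrome, a disorder with patent ductus. It was 13.7-fold higher, at 9.91 ± 0.01 in DA and 6.14 ± 0.11 in aorta (SD, n = 2; limma log2 difference 3.77 ± 0.33 SE, Benjamini-Hochberg adjusted p = 0.000516; Entrez 301285). Clic6, of the intracellular chloride channel family, was 8.6-fold higher, Mab21l2 7.32-fold, the membrane glycoprotein gene Gpm6b 6.34-fold, and Epyc, which encodes a small proteoglycan, 5.39-fold. Genes higher in aorta were led by the short-chain collagen gene Col8a1, which was 8.42-fold lower in DA (log2 difference -3.07 ± 0.26 SE, limma adjusted p = 0.000407), and by the stress-response gene Nupr1, 6.88-fold lower. The amino acid transporter gene Slc7a3, the cadherin gene Cdh8, the transcription factor gene Grhl3, the tight junction gene Cldn1, Spp1 (osteopontin) and the microtubule gene Map2 were between 6.17-fold and 4.68-fold lower. Of the multi-copy families, Spetex2g was 7.6-fold higher in DA, Spetex2el3 5.89-fold and the olfactory receptor gene Or5p60b 5.13-fold.

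In F344, limma called 2028 genes, 1286 higher in DA and 742 lower. Chemosensory receptor genes made up 818 of the higher genes and 0 of the lower, and the remaining genes were 468 higher and 742 lower. The median difference of the receptor genes was 0.79, and 0.48 after repeated quantile normalization and 0.5 after cyclic loess, and that of the brighter genes was -0.17. The share of calls higher in DA was 63.4% as deposited, 87.6% after centring on brighter genes, 19.9% without dim genes and 37% in a test without receptor genes. The called count was 1001 and 646 without F344 DA replicates 1 and 2, and 653 and 860 without F344 aorta replicates 1 and 2.

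Collagens were called lower as a list in F344 DA than in aorta by camera, and elastic fibre genes only by fry (adjusted p = 0.0203). The elastic fibre median was -0.21 as deposited, 0 after centring on brighter genes and -0.17 after repeated quantile normalization and after cyclic loess. Of 12 collagen genes 0 rose and 6 fell (9 fell when adjusted over the list alone), among them Col8a1, Col11a1 by -1.07, Col5a2 by -0.88 and Col3a1 by -0.69 on the log2 scale (camera adjusted p = 2.36e-05, and adjusted p = 0.494 with an estimated correlation). Of 21 genes of elastic fibre assembly 1 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0963), with differences of -1.05 for Ltbp2, -0.96 for the crosslinking enzyme gene Loxl1, -0.66 for Fbln2 and -0.63 for Mfap5. Lox fell by 0.45. Eln (elastin) did not pass, with a difference of -0.25 ± 0.13 SE, and neither did Fbln5 (-0.08 ± 0.12), Fbln1 (0.31 ± 0.19), Vcan (0.35 ± 0.14) or Has2 (0.32 ± 0.27). Of 17 genes of intimal matrix and hyaluronan 0 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.614), namely Spp1, Hyal1 by -0.71 and Hmmr by -0.44.

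Signalling and channel genes moved in both directions. The prostaglandin E receptor gene Ptger4, whose product relaxes the ductus, was 2.41-fold higher in DA (10.64 ± 0.16 against 9.37 ± 0.06, SD, n = 2; limma adjusted p = 0.0146; Entrez 84023), whereas Pla2g4a, Ptger3 and the cyclooxygenase gene Ptgs1 had differences of -1.21, -0.90 and -0.68. Of 25 prostaglandin genes 2 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.299, and 0.0299, lower, with fry). Their median was -0.23 as deposited, -0.02 after centring on brighter genes, -0.2 after repeated quantile normalization and -0.18 after cyclic loess. Of 23 genes of oxygen-sensitive channels and endothelin 6 rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.821). Those that rose included the ATP-sensitive potassium channel genes Abcc9 (1.37) and Kcnj8 (0.91), and those that fell included the potassium channel genes Kcna5 (-1.86 ± 0.21 SE) and Kcnma1 (-1.24). The growth hormone receptor gene Ghr rose by 0.91 and Rgs5 by 0.58, and Epas1 fell by 0.57. Of 14 Notch genes 0 rose and 4 fell (8 fell adjusted over the list alone), Heyl by -0.98, Nrarp by -0.85, Jag2 by -0.66 and Notch3 by -0.54 (camera adjusted p = 0.00112, and adjusted p = 0.392 with an estimated correlation). Of 24 TGF-beta and BMP genes 4 rose and 3 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.765), with a median of -0.23 and a mean of 0.01, and Tgfbi (2.13) and Inhba (1.85) rose most.

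Some positional and contractile genes also differed in F344, although none of their lists was called by camera. Of 17 Hox genes 3 rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.425). Hoxa7 had a difference of -1.70 ± 0.12 SE and Hoxc5 of -1.53, and the 3 that rose were Hoxa4, Hoxb3 and Hoxd3, named after their values were seen. Of 23 transcription factor genes of the cardiac outflow tract and neural crest 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.055), with Tbx3 at 1.10, Tfap2a at 0.97 and Dlx1 at 0.74 beside Tfap2b. Of 19 contractile smooth muscle genes 3 rose, Des by 1.38, Actg2 by 1.24 and Cnn1 by 0.48, and 1 fell, the calcium-binding protein gene Casq2 by -1.76 (4 and 1 adjusted over the list alone, camera adjusted p = 0.0918). Acta2 (0.13 ± 0.11 SE), Myh11 (0.25 ± 0.18) and Myocd (0.21 ± 0.14) did not pass.

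Markers of other cell types moved with the tissue in F344. Of 14 endothelial markers 0 rose and 6 fell in DA (6 fell adjusted over the list alone), with Sox17 at -1.08, Cldn5 at -0.93, Sox18 at -0.82 and Tie1 at -0.73 (camera adjusted p = 0.00292, and adjusted p = 0.392 with an estimated correlation). Of 15 macrophage and myeloid markers 0 rose and 4 fell (6 fell adjusted over the list alone), among them Csf1r at -0.99 (camera adjusted p = 0.00653, and adjusted p = 0.843 with an estimated correlation). Of 11 adventitial fibroblast markers 2 rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.269), with Dpep1 at 1.94 and Pi16 at -1.34. The macrophage call was lost without F344 aorta replicate 1 (camera adjusted p = 0.0589) and with fry (adjusted p = 0.085), which does not compare a list with other genes. Centring on brighter genes moved the list medians from -0.5 to -0.29 for collagens, from -0.36 to -0.16 for Notch, from -0.36 to -0.15 for endothelial cells and from -0.49 to -0.28 for macrophages.

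**Figure D2:**
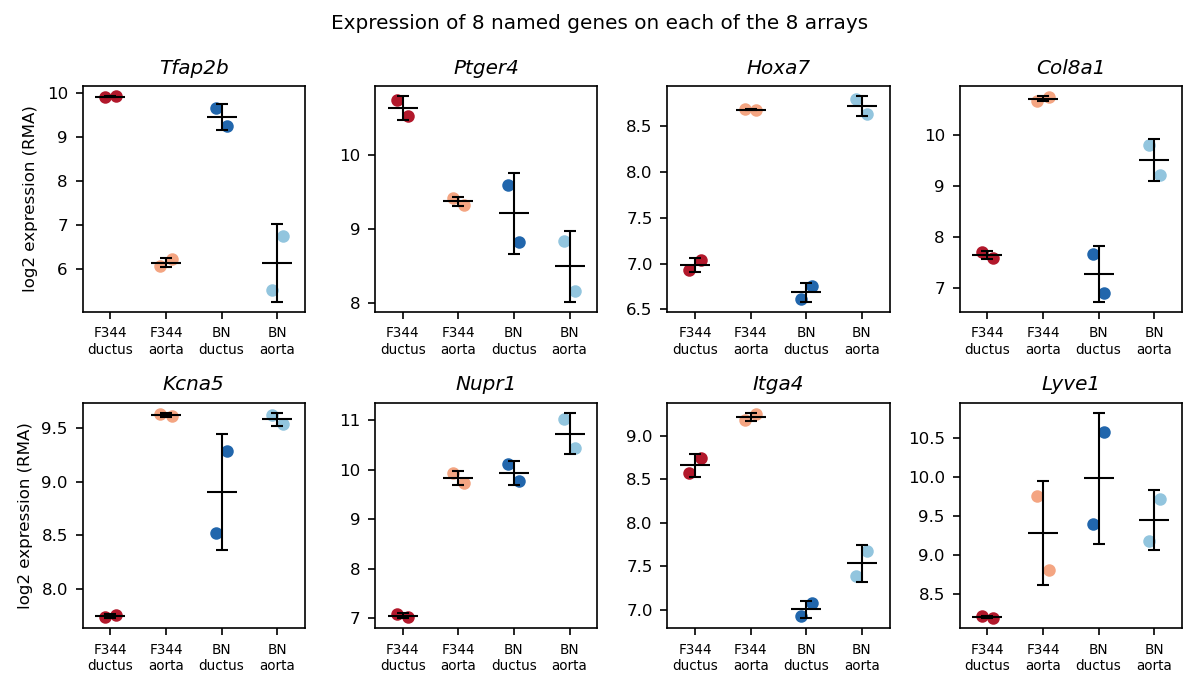
Log2 expression (vertical axis, a separate scale for each gene) of 8 named genes on each of the 8 arrays, by group. Points are arrays, and bars give the mean and SD (n = 2). Tfap2b lies at 9.91 and 9.46 in F344 and BN DA and at 6.14 and 6.13 in the aortas, and Itga4 lies lower in both BN groups, at 7.01 and 7.53, than in F344, at 8.66 and 9.21.

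The same comparison was made within BN. Tfap2b was 10-fold higher in DA than in aorta, at 9.46 ± 0.3 and 6.13 ± 0.88 (SD, n = 2; limma log2 difference 3.32 ± 0.33 SE, adjusted p = 0.00259). Clic6 was 7.48-fold higher, and Tbx20, a transcription factor gene of heart development, 5.24-fold (9.15 ± 1.02 against 6.76 ± 0.19; limma adjusted p = 0.0158), with BN DA arrays at 8.42 and 9.87. Gpm6b, Mab21l2, the adaptor gene Sorbs2, Epyc and the peptide receptor gene Grpr were between 4.6-fold and 3.6-fold higher. Col8a1 was 4.71-fold lower in DA (log2 difference -2.23 ± 0.26 SE), Hoxa7 4.1-fold, Pcp4 3.72-fold, the vasopressin receptor gene Avpr1a 3.34-fold, Fgf7 3.28-fold, Lrrc7 3.14-fold, and Itgbl1 and Cdh8 each 3.12-fold.

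In BN, limma called 262 genes, 143 higher in DA, of which 55 were chemosensory receptor genes, and 119 lower, of which 0 were. The median difference of the receptor genes was 0.39, and 0.2 after repeated quantile normalization and 0.26 after cyclic loess. Without BN aorta replicates 1 and 2 the called count was 16 and 96, without BN DA replicates 1 and 2 it was 600 and 453, without either F344 DA array 114, and without either F344 aorta array 120. A fit with the 4 BN arrays called 16 genes.

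Collagens were again lower in BN DA: of 12 genes 0 rose and 6 fell (11 fell adjusted over the list alone), including Col11a1 at -1.40 and Col3a1 at -1.05 (camera adjusted p = 8.05e-15, and adjusted p = 0.283 with an estimated correlation). Of 11 adventitial fibroblast markers 0 rose and 2 fell, Pdgfra by 1.05 and Scara5 by 0.77, named after their values were seen (2 rose and 4 fell adjusted over the list alone, camera adjusted p = 0.103, and 0.245 with fry). Of 21 genes of elastic fibre assembly 0 rose and 1, Loxl1 at -0.87, fell (3 fell adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.283 with an estimated correlation). Of 17 Hox genes 0 rose and 4 fell, Hoxa7, Hoxc5, Hoxc4 and Hoxd4 (3 rose and 8 fell adjusted over the list alone, camera adjusted p = 0.00698, and adjusted p = 0.505 with an estimated correlation). The Hox median was -0.07 as deposited, -0.02 after centring on brighter genes, -0.24 after repeated quantile normalization and -0.19 after cyclic loess. Of 23 outflow and neural crest transcription factor genes 4 rose and 0 fell (10 and 1 adjusted over the list alone), with Tfap2a at 1.44 and Tbx3 at 0.93 (camera adjusted p = 8.24e-05, and adjusted p = 0.505 with an estimated correlation). The mean of this list was 7.94 and 8.26 on BN DA replicates 1 and 2, against 7.39 and 7.67 on those of BN aorta. Some cardiac genes were also higher on BN DA replicate 2, as given below. Contractile genes were also called higher, although only the phospholamban gene Pln rose, by 0.95 (2 adjusted over the list alone, camera adjusted p = 0.00301, and adjusted p = 0.522 with an estimated correlation). Of 25 prostaglandin genes Ptger3 fell, by 1.52, and 0 rose (0 and 1 adjusted over the list alone, camera adjusted p = 0.0194, and adjusted p = 0.309 with an estimated correlation), and Ptger4 did not pass, with a difference of 0.71 ± 0.27 SE. The Notch list was called lower with 0 members called (3 fell adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.283 with an estimated correlation). Kcnmb1 rose by 1.05, Bmp4 by 1.14, Inhba by 1.44, Tgfbi by 1.52, Rgs5 by 0.84 and Ghr by 0.77. Kcna5 (-0.68 ± 0.21 SE), Lox (-0.21 ± 0.12), Eln (-0.26 ± 0.13) and Ptgs1 (-0.30 ± 0.19) did not pass. The contractile call was lost without BN DA replicate 1 (camera adjusted p = 0.368), without BN aorta replicate 2 (0.286) and with fry (0.245). The prostaglandin call was lost without BN DA replicate 2 (camera adjusted p = 0.227), without BN aorta replicate 1 (0.104), without dim genes (0.614), without receptor genes (0.0541), after repeated quantile normalization (0.0741) and with fry (0.0582). Without dim genes the Hox call (camera adjusted p = 0.887) and the outflow call (0.109, and 0.13 with fry) were lost too.

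By camera, 3 cell type lists were called in BN with 0 of their own members passing over all genes. Lymphatic endothelial markers had a median difference of 0.58 (6 tested, 4 rose adjusted over the list alone, camera adjusted p = 0.00126, and adjusted p = 0.498 with an estimated correlation). Thymocyte and lymphocyte markers had a median of 0.47 (11 tested, 0 rose adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.522 with an estimated correlation) and were high on BN DA replicate 1, as given above. Macrophage and myeloid markers had a median of -0.22 (15 tested, 4 fell adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.522 with an estimated correlation). Without BN DA replicate 1 the thymocyte call (camera adjusted p = 0.651) and the macrophage call (0.109) were lost. With fry the adjusted p was 0.186 for lymphatic, 0.35 for thymocyte and 0.245 for macrophage markers. In lists that were not called, the epithelial keratin gene Krt8 fell by 0.88 and the cartilage gene Acan rose by 1.70, named after their values were seen.

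The tissue differences of the strains, which share no arrays, went largely the same way. Across the 14506 genes, which are not independent replicates, their Pearson correlation was 0.68 (Spearman 0.56), and 0.61 without receptor genes. Of the 2028 genes called in F344, 1879 (92.7%) had the same sign in BN. In both strains 115 genes were called higher in DA, 102 were called lower and 0 were called in opposite directions, where independent lists would share 12.7 and 6.1. Of these, 66 of the higher and 102 of the lower genes were not chemosensory receptor genes. Both contrasts used the same variance estimate of each gene, so genes of low spread are called more easily in both and the lists are not independent.

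Whether the tissue difference depended on strain was tested with the interaction. Limma called 0 genes (smallest adjusted p = 0.107), and 1403 genes had an unadjusted p under 0.05. The 10 genes with the smallest p, none of which passed in this fit, were Glp1r, Nupr1, Sphkap, Ppargc1a, Npr3, Postn, Tppp3, Tmem100, Or1o11 and Itgbl1. The incretin receptor gene Glp1r was at 7.73 ± 0.09 in DA and 9.29 ± 0.18 in aorta of F344 and at 10.02 ± 0.59 and 9.44 ± 0.05 in BN (SD, n = 2; interaction 2.14 ± 0.33 SE, limma adjusted p = 0.143). The matrix gene Postn was at 10.52 ± 0.13 and 12.41 ± 0 in F344 and 12.17 ± 0.11 and 12.69 ± 0.03 in BN. Kcna5 (1.18 ± 0.30 SE, limma adjusted p = 0.284) and Ptger4 (-0.55 ± 0.38, limma adjusted p = 0.688) did not pass. Some genes were called in fits without 1 of the BN DA arrays. There BN DA held a single array, and its own spread, the widest of the groups, was left out of the test. Such calls do not show an interaction hidden by 1 array.

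As a set, DA-aorta differences were smaller in BN. Of 2403 genes called in the tissue contrast averaged over strains, 1942 (80.8%) differed less in BN, with a median size of 0.43 against 0.71 in F344. The rotation test roast gave p = 0.0329, and an exact permutation of strain labels within tissues could not go below 0.0556. The share was 83.9% of 1464 DA-high genes and 75.9% of 939 aorta-high genes, and 74.5% of 1532 genes other than receptors (roast p = 0.0388, rotation rather than exact test). By the same rotation rather than exact test, without BN DA replicate 1 it was 67.5% (p = 0.238), without BN DA replicate 2 69.8% (p = 0.0314), without BN aorta replicate 2 74.1% (p = 0.112), without F344 DA replicate 2 83.7% (p = 0.0516), without F344 aorta replicate 1 83.2% (p = 0.0559), and after centring on brighter genes 84.2% (p = 0.0522). By rotation, not an exact test, it was 77.9% (p = 0.0049) after repeated quantile normalization and 75% (p = 0.0119) after cyclic loess, and among genes other than receptors 72.3% (p = 0.0192) and 68.2% (p = 0.0597). Endothelial markers (median interaction 0.45; 3 of 14 higher adjusted over the list alone, camera adjusted p = 0.000124, and adjusted p = 0.359 with an estimated correlation), lymphatic endothelial markers (0.84; 4 of 6, camera adjusted p = 0.000124, and adjusted p = 0.559 with an estimated correlation) and cell cycle genes (0.24; 0 of 22, camera adjusted p = 0.000314, and adjusted p = 0.868 with an estimated correlation) were called as lists, with 0 members passing over all genes. The cell cycle median was 0.08 after centring on brighter genes, 0.13 after repeated quantile normalization and 0.12 after cyclic loess, and the call was lost with the last 2 (camera adjusted p = 0.15 and 0.0896). The endothelial median was 0.29 after centring. With fry the adjusted p was 0.171 for endothelial markers, 0.295 for lymphatic markers and 0.308 for cell cycle genes.

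**Figure D3:**
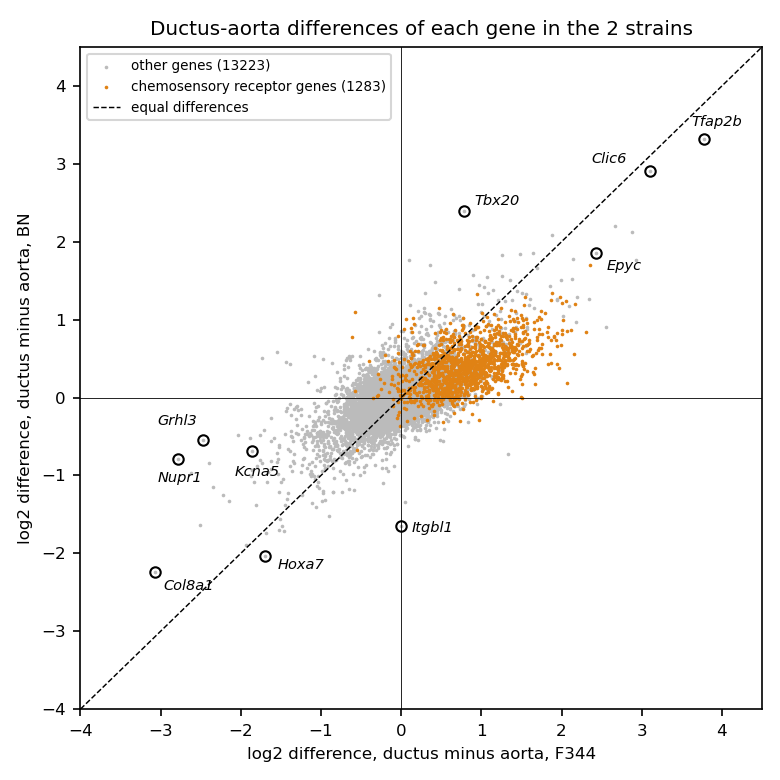
Log2 difference between DA and aorta of each of the 14506 genes in F344 (horizontal axis) and BN (vertical axis). Orange points are the 1283 chemosensory receptor genes, grey points the other 13223 genes, circles named genes, and the dashed line marks equal differences. Receptor genes lie to the right, with medians of 0.79 in F344 and 0.39 in BN.

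The strains were then compared within DA. Nupr1 was 7.39-fold higher in BN DA, at 9.94 ± 0.24 against 7.05 ± 0.05 (SD, n = 2; limma log2 difference 2.89 ± 0.20 SE, adjusted p = 0.00144). Glp1r was 4.87-fold higher, the zinc finger gene Zfp347 4.84-fold, the sodium channel subunit gene Scn3b 4.73-fold, the cold-sensing channel gene Trpm8 4.34-fold, Grhl3 4.24-fold, the synaptic vesicle gene Sv2c 4.17-fold and the fatty acid receptor gene Cd36 4.09-fold. Among these, the BN DA replicates had an SD of 1.37 for Scn3b, 1.13 for Grhl3 and 0.99 for Sv2c. Lower in BN DA were Itgbl1, 4.21-fold (8.22 ± 0.37 against 10.29 ± 0.03), the integrin gene Itga4, 3.14-fold, Ptger4, 2.7-fold (9.21 ± 0.55 against 10.64 ± 0.16; limma adjusted p = 0.0256), the tenascin gene Tnn, 2.56-fold, and the lipid transporter gene Mfsd2a, 2.38-fold. The receptor genes Or11i1, Or7r1 and Olr1471 were between 2.65-fold and 2.34-fold lower.

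Limma called 657 genes in DA, 353 higher in BN and 304 lower, and 209 of the lower genes were chemosensory receptor genes, whose median difference was -0.48, and -0.3 after cyclic loess. The remaining genes were 352 higher and 95 lower. The share of calls higher in BN was 53.7% as deposited, 23.7% after centring on brighter genes, 84.7% without dim genes and 79.9% in a test without receptor genes. Without F344 DA replicates 1 and 2 the called count was 24 and 13, without BN DA replicate 2 it was 1233, and without either F344 aorta array 306, while a fit with the 4 DA arrays called 118.

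Of 23 genes of oxygen-sensitive channels and endothelin, 4 were higher in BN DA and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.118, and 0.0479, higher, with fry). The direction of the list depended on the scaling. Its median was 0.08 as deposited, -0.02 after repeated quantile normalization, -0.06 after centring on brighter genes and -0.01 after cyclic loess. Kcnmb1 (1.18), Kcna5 (1.15 ± 0.21 SE) and Kcnma1 (0.85) were among the higher and Abcc9 (-0.93) among the lower. The soluble guanylate cyclase genes Gucy1a1 and Gucy1b1, the sensors of nitric oxide, rose by 0.66 and 0.61 among 20 genes of that list, of which 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.842). Of 17 genes of intimal matrix and hyaluronan 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.137, and 0.0479, higher, with fry), with the proteoglycan gene Acan at 1.87 and Spp1 at 1.66. The median of this list was 0.24 as deposited, 0.09 after centring, 0.16 after repeated quantile normalization and 0.19 after cyclic loess. Vegfa rose by 1.14, Tbx20 by 1.80 and Casq2 by 1.55, and Hoxa5 fell by 0.99. Tfap2b (-0.45 ± 0.33 SE), Fbln1 (-0.77 ± 0.19), Eln (-0.09 ± 0.13), Acta2 (-0.08 ± 0.11), Has2 (0.75 ± 0.27) and Jag1 (0.08 ± 0.14) did not pass.

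Cell cycle genes and markers of several cell types were higher in BN DA. Of 22 cell cycle genes 5 rose and 0 fell (8 rose adjusted over the list alone), among them Bub1 at 0.74, Kif20a at 0.61, Nusap1 at 0.59 and Kif11 at 0.57 (camera adjusted p = 1.87e-06, and adjusted p = 0.583 with an estimated correlation). Of 6 lymphatic endothelial markers 4 rose (6 adjusted over the list alone), the chemokine gene Ccl21 by 1.87, the hyaluronan receptor gene Lyve1 by 1.78, the transcription factor gene Prox1 by 1.06 and the VEGF receptor gene Flt4 by 0.92 (camera adjusted p = 4.2e-05, and adjusted p = 0.583 with an estimated correlation). Of 14 endothelial markers Flt1 rose by 0.65 and Sox17 by 0.63 (7 adjusted over the list alone, camera adjusted p = 0.00161, and adjusted p = 0.583 with an estimated correlation). Of 15 macrophage and myeloid markers C1qc rose by 0.81 (4 adjusted over the list alone, camera adjusted p = 0.0101, and adjusted p = 0.693 with an estimated correlation). Thymocyte and lymphocyte markers had a median difference of 0.50 and were not called (1 of 11, Cd4, rose by 1.01, and 1 adjusted over the list alone, camera adjusted p = 0.0577). The endothelial call was lost without BN DA replicate 1 (camera adjusted p = 0.0881) and without dim genes (0.0559). The macrophage call was lost without BN DA replicate 2 (camera adjusted p = 0.0853), without dim genes (0.0583) and with fry (0.183), and the lymphatic call with fry (0.0553). Centring moved the list medians from 0.31 to 0.16 for cell cycle genes, from 0.42 to 0.27 for endothelial cells and from 0.41 to 0.26 for macrophages.

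In aorta, fewer genes were called between the strains. Trpm8 was 4.73-fold higher in BN aorta (9.25 ± 0.15 against 7.01 ± 0.09, SD, n = 2; limma log2 difference 2.24 ± 0.23 SE, adjusted p = 0.00948), the neurotrophic factor receptor gene Gfra1 3.88-fold, the DNA ligase gene Lig4 2.96-fold, the relaxin receptor gene Rxfp1 2.64-fold, and Serinc2, Slitrk5, Crispld1 and the glycogen phosphorylase gene Pygl between 2.53-fold and 2.36-fold. Itga4 was 3.21-fold lower, Scand1 3.1-fold, Echdc2 2.69-fold, the growth factor binding protein gene Igfbp6 2.61-fold, the fatty acid oxidation gene Acaa2 2.32-fold, the natriuretic peptide receptor gene Npr3 2.27-fold, Shisa3 2.15-fold and Vps52 2-fold, and Pln fell by 0.91. None of the 18 ductus genes passed, Ptger4 having a difference of -0.88 ± 0.27 SE.

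Limma called 23 genes in aorta, 12 higher in BN and 11 lower. The called count was 0 without replicate 1 of F344 aorta or of BN aorta (with limma, 757 genes had an unadjusted p under 0.05 on all arrays), 1 without replicate 2 of either, 8 without either F344 DA array and 69 without either BN DA array, and a fit with the 4 aorta arrays called 56. With 0 members passing, immediate early genes had a median of -0.26 (20 tested, 3 fell adjusted over the list alone, camera adjusted p = 0.000521, and adjusted p = 0.72 with an estimated correlation). Macrophage and myeloid markers had a median of 0.26 (15 tested, 1 rose adjusted over the list alone, camera adjusted p = 0.004, and adjusted p = 0.893 with an estimated correlation), and erythroid markers of 0.36 (10 tested, 0 rose adjusted over the list alone, camera adjusted p = 0.0164, and adjusted p = 0.893 with an estimated correlation). Without F344 aorta replicate 2 both marker calls were lost (camera adjusted p = 0.368 for each), as they were without BN aorta replicate 1 (0.136 for macrophages and 0.265 for erythroid cells) and with fry (0.896 for each). The erythroid call was also lost without dim genes (camera adjusted p = 0.153), after cyclic loess (0.0505) and after repeated quantile normalization (0.0632), and the immediate early call with fry (0.33).

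The strain differences of the tissues, which share no arrays, had a Pearson correlation of 0.37 over genes (Spearman 0.3). In both tissues 11 genes were called higher in BN, 7 were called lower and 0 were called in opposite directions, where independent lists would share 0.3 and 0.2. Here too the contrasts used the same variance estimate of each gene. Trpm8, Gfra1 and Lig4 were among the higher and Itga4, Scand1 and Echdc2 among the lower. Averaged over tissues, limma called 384 genes between strains, 236 higher in BN and 148 lower. Of the lower genes 71 were chemosensory receptor genes. The share of calls higher in BN was 61.5% as deposited, 37.4% after centring on brighter genes, 75.4% without dim genes, 75.6% in a test without receptor genes and 45.7% without BN DA replicate 2. The count was between 55 and 123 without any 1 of the F344 or BN aorta arrays or F344 DA arrays, and 1015 and 830 without BN DA replicates 1 and 2.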

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

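The tests of the receptor genes, of mixing, of background and of probe sequence were chosen after the results were seen, and the rotation test of bright genes replaced a binomial interval after its value was seen. The test of a narrower range first also asked for p under 0.05 without receptor genes, and was limited to all genes after those values were seen. The interaction, the list tests and the rotation test of smaller differences in BN were fixed before the data were examined.

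Chemosensory receptor genes, which no comparison of the study was about, were higher in DA in both strains. A general rise of dim values or a narrower range of the DA arrays is argued against as the whole cause, because receptor genes exceeded other genes of the same level by a median of 0.62 in F344 (0.58 to 0.64 over pairs of arrays) and 0.34 in BN. Expression of particular receptors in the ductus is argued against as the whole cause, because 96.7% of receptor genes were higher in F344 DA. A shift of the whole class would raise nearly all of them whether or not some were also expressed, so expression of some is not excluded. Target that binds sequence shared by many gene copies, from genomic DNA or cross-hybridising RNA, remains a candidate explanation. At the same level, receptor probe sets that match several genes exceeded those that match 1 gene by 0.46 in F344 (0.32 to 0.51). In BN this excess was 0.47, although the rise over other genes was 0.34 there against 0.62 in F344. Probe sets of other families that match several genes exceeded theirs by 0.08 in F344 and 0.1 in BN. They were matched on level only, so they do not decide whether shared sequence in general accounts for the rise. The source of the target was not tested.

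The difference between tissues was smaller in BN for 80.8% of the 2403 genes called in the tissue contrast averaged over strains. The rotation test roast, not an exact test, gave p = 0.0329 on all arrays, and the result depended on single arrays, as given above. On the deposited scale only, the mean of the Hox genes argues against aorta tissue mixed into the BN ductus pools as the sole cause, provided that such aorta had the Hox levels of the sampled aorta. A share of 23.1% of aorta would give the smaller differences of 76 other aorta-high genes and a mean of -0.63 for the 7 Hox genes called higher in aorta. These had -0.98 (SE 0.04) in BN and -0.91 in F344, and the SE leaves out the error of the fitted share. Hoxb7, Hoxb8 and Hoxb9 differed less in BN (-0.61, -0.51 and -0.53) than in F344 (-0.69, -0.59 and -0.72), whereas Hoxa7, Hoxc4, Hoxc5 and Hoxd4 differed more. The comparison was not repeated after rescaling, which moved Hox values. After repeated quantile normalization the median of all Hox genes tested was -0.4 in F344 and -0.24 in BN, against -0.09 and -0.07 as deposited. Hoxc5 then differed by -1.86 in F344 and -1.72 in BN, and Hoxa7 by -1.63 and -1.96. Mixing is therefore not decided beyond the deposited scale. Whether a narrower range of the F344 DA arrays was the whole cause is not decided by the rescaled values. The test was limited to all genes after the values without receptor genes were seen, and that set includes receptor genes. By rotation, not exact, tests, the share over all genes was 77.9% after repeated quantile normalization (p = 0.0049) and 75% after cyclic loess (p = 0.0119). As deposited, 92% of 871 called receptor genes differed less in BN. The median difference of all receptor genes after the rescalings was 0.48 and 0.5 in F344, against 0.2 and 0.26 in BN. Without BN DA replicate 1 the share over all genes was 67.5% as deposited, 67.9% after quantile normalization and 65.8% after loess. Without replicate 2 it was 69.8%, 64.6% and 62.5%. A narrower range together with raised background cannot be told apart from a strain difference: among genes other than receptors the share was 72.3% (p = 0.0192) and 68.2% (p = 0.0597) after these rescalings, and 62% of 208 bright DA-high genes other than receptors differed less in BN, with p = 0.325 by rotation in place of an exact binomial interval (55.0% to 68.6%) that takes genes as independent. A difference between the strains in the ductus itself stays open and untested.

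Of the 18 genes called between strains in the same direction in both tissues, 61.1% were lower in F344. F344 sequence differences at probes drawn from the BN reference could lower F344 signal in both tissues, which would make most such genes lower in F344. With 11 of 18 lower (exact binomial 95% interval 35.7% to 82.7%, two-sided exact p = 0.481), this cannot be told apart from differences in expression, because the genes are few. Inherited expression differences between the strains stay open and were not tested.

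In 3 lists the interaction differed from that of other genes by camera. The camera adjusted p was 0.000124 for endothelial cells, 0.000124 for lymphatic endothelial cells and 0.000314 for cell cycle genes. With an estimated correlation or with fry 0 of the lists passed. The cell cycle list also failed after repeated quantile normalization (camera adjusted p = 0.15) and cyclic loess (0.0896).

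Among 13582 probe sets that the annotation does not list, 844 were higher and 313 lower in F344 DA than in F344 aorta in a test of every probe set, and among 323 probe sets that match several genes 143 were higher and 3 lower.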

How the results depend on the processing

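Leaving out receptor genes, cyclic loess, and for the lists repeated quantile normalization and left-out arrays were chosen after the data were seen; the other alternatives were planned. Named genes were fitted again with a variance trend, the mean of probe sets, repeated quantile normalization, cyclic loess, the block below and each array left out, and 0 of 194 called values changed sign. Of these, 49 were lost under at least 1 of the first 5 settings and 144 in at least 1 fit without an array; without F344 DA replicate 2, 112 were lost, and without BN DA replicate 2, 10. A left-out array leaves a group with 1 array, assumed to vary like the other groups. The cause of the moves below was not tested, except that fewer genes or arrays were tested where some were left out.

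Counts in F344 between tissues were 628 without dim genes, 3710 with array weights, 982 without receptor genes, 667 at 2-fold, 3363 with 4 arrays and 646 to 2850 without 1 array. In BN between tissues they were 170 without dim genes, 88 over every probe set, 100 with array weights, 100 at 2-fold, 16 with 4 arrays and 16 to 600 without 1 array. Between strains in DA they were 412 without dim genes, 326 with array weights, 408 without receptor genes, 156 at 2-fold, 118 with 4 arrays and 13 to 1233 without 1 array, and in aorta 54 with array weights, 56 with 4 arrays and 0 to 69 without 1 array. The interaction had 0 to 56 without 1 array. The averaged tissue contrast had 887 without dim genes, 1332 without receptor genes, 289 at 2-fold and 1361 to 3184 without 1 array, and the averaged strain contrast 211 after centring, 40 at 2-fold and 55 to 1015 without 1 array. The balance of higher and lower calls turned in several counts. In BN the share higher in DA was 54.6% as deposited, 40.6% without dim genes and 43.4% without receptor genes, and the share higher in BN DA fell below that of lower calls after quantile normalization (49.5%) and loess (47.5%), with 4 arrays (45.8%) and without BN DA replicate 2 (40.4%, and 45.7% over both tissues). Shares of calls higher in DA over both strains were 60.9% as deposited, 82.4% after centring, 22.1% without dim genes and 38.7% without receptor genes. Centring moved the median of all genes to 0.16 in F344 between tissues and to -0.15 between strains in DA. Under the 4 scalings 0 of the medians of 24 lists called by camera and of the receptor genes changed sign, but 55 of 141 medians of lists that camera did not call did. Among the latter, lists that only fry called moved too. Centring took oxygen-sensitive channels between strains in DA from 0.08 to -0.06. In F344 between tissues it took elastic fibre genes from -0.21 to 0 and prostaglandin genes from -0.23 to -0.02.

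The share of genes with a smaller difference in BN was 84.2% (p = 0.0522) after centring, 68.2% (p = 0.0597) after loess with receptor genes left out and 67.5% to 84.7% without 1 array, with p from 0.0049 to 0.238 over all alternatives, apart from arrays left out after rescaling, by rotation, not exact, tests. Of 24 list calls, 0 held with an estimated correlation, fry called 13, of which 9 were shared, and 38 were called without dim genes, of which 17 were shared.

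The labels do not say whether equal replicate numbers mark a shared pool, litter or batch. Deviations of equally numbered arrays correlated at 0.03 to 0.52, and erythroid markers were higher on replicate 1 in each group, so a shared source is not excluded. With the replicate number as a block, counts were 548 in BN between tissues (262 without it) and 1583 between strains in DA (657 without it). They were 966 in the averaged strain contrast (384 without it) and 2 in the interaction (Nupr1 and Ppargc1a, 0 without it). With the block, 1 called value of a named gene was lost. How far signal over background limits precision was not tested beyond the fits without dim genes.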

Other observations

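The tests of lymphatic markers and the comparison of the BN DA replicates were chosen after the results were seen, and the counts of other splits of the arrays were planned.

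The BN DA replicates differed in groups of genes that the comparisons above do not describe, named here after their values were seen. Of the 200 genes at least 1 log2 unit apart, 88 were higher on replicate 2 and 112 on replicate 1. The T cell genes Rag1, Cd3g and Cd8b were at 8.2, 6.84 and 7.09 on replicate 1 and at 5.83, 4.77 and 5.7 on replicate 2. The cardiac genes Gata4, Tnnt2 and Actc1 were at 8.9, 9.24 and 9.71 on replicate 2 and at 6.95, 7.47 and 7.98 on replicate 1, whereas the cardiac troponin gene Tnnc1 was at 9.13 and 11.02. The fixed list of cardiac muscle markers differed little, with means of 7.09 and 7.24 on BN DA replicates 1 and 2. On those of BN aorta its means were 6.87 and 6.99. Tbx20, named above, was at 9.87 on replicate 2 and 8.42 on replicate 1, and at 7.32 and 7.37 in F344 DA. Ribosomal protein genes made up 15 of the genes higher on replicate 1 and 0 of those higher on replicate 2, with Rps28 at 12.25 and 10.63 and Rpl37a at 11.43 and 10.04 on replicates 1 and 2 of BN DA, and at 11.62 and 10.73 and at 11.15 and 10.31 on those of BN aorta. The mitochondrial genes Ndufa6 and Atp5mg were at 9.15 and 8.65 on BN DA replicate 1 and at 7.57 and 7.22 on replicate 2, and at 8.84 and 8.32 and at 8.11 and 7.46 on those of BN aorta. Of the 20 oxidative phosphorylation genes fixed as a list, 1 was among those higher on BN DA replicate 1, and their means were 10.12 and 9.66 in BN DA and 9.91 and 9.82 in BN aorta. The haemoglobin gene Hbb was higher on replicate 1 in each group, at 13.01 and 10.58 in BN DA, 12.7 and 10.98 in BN aorta, 13.02 and 11.87 in F344 DA, and 12.53 and 11.55 in F344 aorta.

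A hypothesis for the higher lymphatic markers in BN DA is that the BN ductus pools held more lymphatic vessel tissue. The values do not decide it, since these markers were examined because their list was called: 6 of 6 were higher on both BN DA arrays than on both F344 DA arrays, with Lyve1 at 9.39 and 10.57 against 8.21 and 8.19 and Ccl21 at 9.61 and 8.27 against 7.19 and 6.95. A lower share of smooth muscle alone would raise markers of all other cell types present alike. The lymphatic list rose by 1.11 (SE 0.21) more than the mean of 14 other cell type lists. That excess does not decide the question, since the list was examined for its rise in this contrast. The 14 lists also include cell types that may be scarce in the vessels. Whether lymphatic vessel tissue came with the dissection or belongs to the BN ductus was not tested.

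Chance was assessed over the 35 splits of the 8 arrays into 4 and 4, with the split as the only term. The tissue split called 1362 genes, the highest of the other splits 24, and 1 of 35 splits called as many, the fewest the count allows. All other splits mix DA and aorta arrays in both parts, which adds tissue differences to their residual spread. A chance split is thus unlikely at this limit but not excluded, because the labels do not state that replicates came from separate animals or litters. The strain split called 24 genes, and 2 of 35 splits called as many, the other being the tissue split with 1362 genes, which points to the tissue structure of the samples. With that split among the 35 the count could hardly be lower, so chance cannot be excluded by it, and it says little about the strains. Compared within each tissue, 11 genes were called higher and 7 lower in BN in both, where independent lists would share 0.3 and 0.2, although both used the same variance estimate of each gene.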
